A study of Paulownia elongata with 2 samples.

How the data were processed

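RNA from leaves of Paulownia elongata, a fast-growing tree, was sequenced as cDNA libraries from control plants and from plants irrigated with NaCl solution. The labels hold 2 records, one per treatment, and state that each merges 2 replicates. Each record carries 2 library files, so each library was taken here as 1 replicate, giving 2 control libraries (AC1 and BC1) and 2 salt libraries (SS1 and SS2). Nothing in the labels says whether the 2 libraries of a treatment came from separate plants, so p-values measure the spread between these libraries only, which may be partly technical. The record for the salt treatment names its libraries SS2 and SS4, whereas its deposited files are SS1 and SS2. The files were used under the treatment of the record that holds them.

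Per the submitters' processing notes, the tools named are Bowtie2 2.1.0, TopHat2 2.0.9, Cufflinks 2.1.1, Cuffdiff 2.2.1 and RSEM 1.3.0. Their settings, the assembler and any read filter are not given in the sources used here. Per the file headers, each library file holds RSEM gene results with an expected count, a length, a TPM and an FPKM value for each assembled gene. The expected counts deposited by the authors are estimates that need not be whole, because RSEM shares reads that match several isoforms or genes, and 3556 to 4746 values per library were not whole. The TPM values deposited by the authors are scaled by length and sum to the same total in every library. FPKM values were not used. The deposited normalized matrix is a signal made by the authors from the expected counts: each column was the library's expected count times 1 constant, namely 1.164 for AC1, 1.161 for BC1, 0.792 for SS1 and 0.904 for SS2.

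The authors deposited 3 tables of comparisons. Per the file headers, 2 of them give for each assembled gene posterior probabilities of equal and of different expression, which are fractions, with fold ratios of control over salt. The shorter one equals the 646 assembled genes of the longer one with a posterior probability of equal expression of at most 0.0004. Its group means equal the means of the normalized AC1 and BC1 columns and of the SS1 and SS2 columns, which fixes its direction. The third is a Cuffdiff table, in which the authors deposited log2 fold changes, p-values and q-values per locus. It calls its conditions q1 and q2 and does not say which treatment each is, so no direction was read from it.

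The features are 58997 assembled genes in 39968 assembly components, identified by IDs such as TR26363|c0_g1. The component is the part of the ID before the bar. The median assembled length was 410 bases. The files pair no ID with a gene name, product or sequence, and no reference was used here. The 22 gene lists fixed in advance (such as abscisic acid signalling, ion transport and photosystem subunits) therefore could not be matched to any ID and were not tested. Copies or alleles of 1 gene may be assembled apart, so reads may be split between assembled genes, and this could not be resolved without sequences.

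Expected counts were rounded to whole numbers. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment, at an adjusted p under 0.05, with no covariate. A standard error of a log2 fold change is the fold change divided by the square root of the F statistic. CPM values are TMM-scaled, except where library totals are named, and correlations and log2 ratios between single libraries used library totals. Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, no filter on low counts, a mean of at least 10 counts, limma 3.58.1 on log2(TPM + 1) with a mean TPM of at least 1, the same with a pseudocount of 0.1 or with no filter, each library left out in turn, a replicate block, a test against a 1.5-fold change and an adjusted p under 0.01. The block paired AC1 with SS2, both labelled replicate 1, and the remaining libraries, although the mismatch of names leaves the numbers of the salt libraries in doubt. Adjusted p-values that DESeq2 left out were kept as missing. Assembled genes with at least 10 counts in both libraries of a treatment and 0 in both of the other were also counted, a measure chosen after the data were seen, as were the classes of abundance by rank. Counts were thinned, where stated, to 2631210 per library outside the 50 most abundant assembled genes, in 20 draws. Python 3.11.15 with scipy 1.17.1 was used for the remaining tests.

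With IDs only, the rule for named genes, fixed before the data were examined, took the 2 highest and the 2 lowest assembled genes by smallest adjusted p, with ties going to the larger fold change. At the smallest adjusted p, 187 assembled genes were tied. The scripts were tested on simulated data: negative binomial counts for 20018 assembled genes at the real means and library sizes. Each assembled gene had the dispersion that edgeR estimated for it, the same in both treatments. There were 200 changed assembled genes, in 5 simulations of salt against control. Of those changed 16-fold, edgeR recovered 38.8% and DESeq2 88.2% on average. Of those changed 4-fold, edgeR recovered 0.2% and DESeq2 17.6%. False calls averaged 4.8 per simulation for edgeR and 70.4 for DESeq2. The estimated median size was 1.95 on the log2 scale for the 4-fold change and 4.05 for the 16-fold change with edgeR.

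The libraries held 3752659 to 4682437 rounded counts. A count of 0 allows up to 3 counts, which is 0.641 to 0.799 CPM by library total. Such limits and the Wilson intervals of 95% given for shares cover counting error only, since reads were not tagged as separate molecules. With 2 libraries against 2, the smallest two-sided p an exact permutation test can give is 0.333.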

Results

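The study asked which transcripts differ in leaves of Paulownia elongata after irrigation with salt water. Potted trees received 1.5 L of 125 mM NaCl daily for 10 days, and controls received water. Expression was measured by RNA-seq in 2 control libraries (AC1 and BC1) and 2 salt libraries (SS1 and SS2). The libraries held 4682437 (AC1), 3752659 (BC1), 3969740 (SS1) and 4384738 (SS2) rounded expected counts over 58997 assembled genes. At least 1 count was found for 48219 assembled genes in AC1, 45556 in BC1, 52134 in SS1 and 48292 in SS2. The 2 libraries of a treatment were not copies of each other. A chi-square test of their counts gave a statistic per degree of freedom of 38.0 for the control pair and 14.9 for the salt pair, where sampling noise alone gives about 1.

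A few assembled genes took a large share of the counts in every library, and their share varied widely within each treatment. The component with most counts over the 4 libraries pooled, TR15237, singled out after its values were seen, consists of 7 assembled genes. It took 29.34% of AC1 (95% Wilson interval 29.298 to 29.381), 4.38% of BC1 (4.357 to 4.398), 2.62% of SS1 (2.600 to 2.631) and 11.64% of SS2 (11.614 to 11.674). Its mean share was 16.9% ± 17.6 (SD, n = 2) in control and 7.13% ± 6.38 (SD, n = 2) in salt, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.667). The 500 most abundant assembled genes of each library together held 53.5% ± 9.20 (SD, n = 2) of control counts and 39.7% ± 7.78 (SD, n = 2) of salt counts. Both control libraries lay above both salt libraries in this share, and the exact permutation test gave p = 0.333, the smallest that this design allows.

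**Figure D1:**
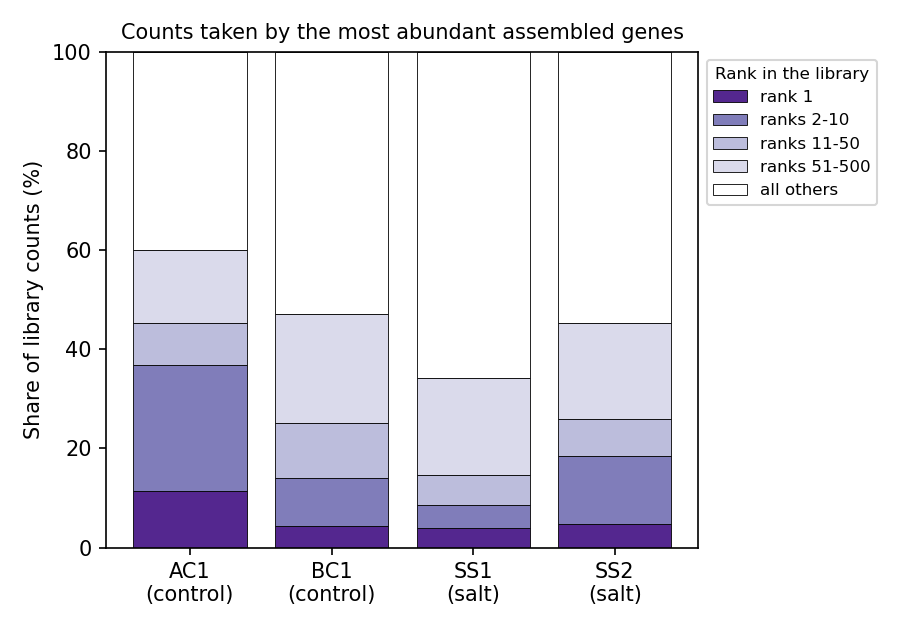
Stacked bars give the share of each library's counts (%) held by its most abundant assembled genes, split by rank within the library, for 2 control and 2 salt libraries. The top 500 hold 60.02% of AC1 and 47.01% of BC1, against 34.18% of SS1 and 45.18% of SS2.

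Among the 50 most abundant assembled genes, 19 had both salt libraries below both control libraries and 1 had both above, where unordered libraries would give 16.7% in each direction. The median log2 fold change of these 19, which came from 19 components, was -1.37, ranging from -4.01 to -0.43. None passed the adjusted threshold in edgeR, where the smallest adjusted p among the 50 was 0.496, and DESeq2 called 5 of the 50. When libraries were scaled to their total counts instead of by TMM, 9 lay below (18%, close to that 16.7%) and 5 above (10%). The median log2 ratio of the 50 was -1.17 with TMM and -0.65 with library totals, beside -0.02 and 0.44 for the 15018 tested assembled genes outside the 5000 most abundant. A change of scaling shifts all classes by a similar amount, so the gap between them cannot test the scaling. The 50 were picked by mean CPM, which favours assembled genes with a high value in a single library. For the next 450 by abundance, 22% lay above and 32.9% below with TMM, and 34.2% above and 17.6% below with library totals. For the next 4500 the shares were 17.3% and 24.8% with TMM, and 39.6% and 6.2% with library totals. For the remaining 15018 tested assembled genes they were 21% and 18.1%, and 43% and 5.3%, so the balance of each class below the top 50 is largely set by the scaling.

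The main comparison, salt against control, found no assembled gene past an adjusted p of 0.05 among 20018 tested with edgeR. The smallest adjusted p was 0.448. At an unadjusted p under 0.05 there were 1749 assembled genes, 782 higher and 967 lower in salt, where 1001 would be expected by chance. The 2 other pairings of the 4 libraries gave 545 and 828. Each mixes the treatments, so any salt effect adds to its spread, and it sets no chance level for this excess. This excess depends on the libraries used: the number rose without either control library and fell below the chance expectation without either salt library. With limma on log2(TPM + 1), 0 passed and the split at an unadjusted p under 0.05 was 3682 higher and 1213 lower. The median log2 fold change of the tested assembled genes was -0.05 with edgeR and 0.30 with that limma fit. That fit differs from the edgeR fit in test, transformation, library scaling, length scaling and filter (56781 assembled genes tested). TPM values sum to the same total in every library and were not TMM-scaled. Scaling counts to library totals in place of TMM moved the median log2 ratio of the 15018 least abundant tested assembled genes from -0.02 to 0.44. With RLE in place of TMM the edgeR split was 779 higher and 965 lower. Between the 2 control libraries alone, 5561 assembled genes differed at least 2-fold, and between the 2 salt libraries 3167. The biological coefficient of variation was 48.4%. The count of calls depends on the libraries used: edgeR made calls without AC1 and without BC1, but none without SS1 or without SS2. A fit with 1 control library takes its spread from the salt pair, whose libraries lay closer together. Calls of such fits are therefore no measure of what either control library hides.

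DESeq2, run as an alternative, called 345 assembled genes at an adjusted p under 0.05, of which 169 were higher and 176 lower in salt. In simulations of this comparison it made 70.4 false calls on average. Only 200 assembled genes were changed there, so the false share in the simulations was well above the 0.05 that the threshold sets. Those simulations gave both treatments the same dispersion, although the control libraries lay further apart, so they do not measure the false share of the 345. The fitted changes of those called higher had a median size of 3.99 on the log2 scale (quartiles 3.07 and 5.60), and those called lower 3.28 (quartiles 2.65 and 4.07). Among those called higher, 25 had no count in either control library, and among those called lower, 3 had no count in either salt library. With these set to their lower bound, at 3 counts per library, the median sizes were 3.51 and 3.26. DESeq2 called 1015 assembled genes without AC1, 306 without BC1, 44 without SS1 and 88 without SS2.

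**Figure D2:**
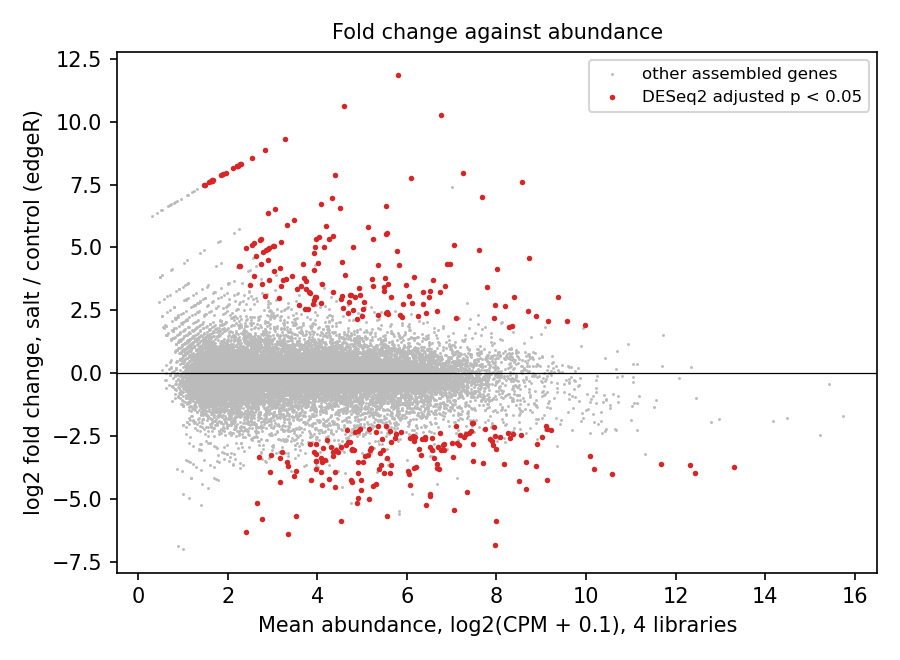
Each of 20018 points is an assembled gene, with its mean abundance over 4 libraries on the x axis (log2 of CPM + 0.1) and its edgeR log2 fold change, salt over control, on the y axis. Red points are the 330 of these called by DESeq2, 166 higher and 164 lower in salt, while edgeR called none.

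Assembled genes present under 1 treatment and undetected under the other were mostly salt ones. With at least 10 counts in both libraries of a treatment and 0 in both of the other, 42 assembled genes from 41 components were found in salt and 3 in control. The salt set had a median length of 718 bases and median counts of 26.5 in SS1 and 17.5 in SS2. The 2 other ways of pairing the 4 libraries gave 2 to 7 such assembled genes per pair. With a minimum of 5 counts the salt pair held 118 and the control pair 20, and the pairs of the other pairings held 59 and 18, and 39 and 41. Among the 42, 15 stood in the authors' deposited table of 646. With a minimum of 20 counts, 15 remained in salt and 0 in control. Without BC1 the numbers were 118 in salt and 35 in control, without AC1 243 and 47, without SS1 83 and 35, and without SS2 142 and 14. Leaving out a library relaxes the rule, so these numbers could only rise from 42 and 3. The control libraries held fewer counts outside the 50 most abundant assembled genes (2631210 and 2872561) than the salt libraries (3454044 and 3283034). After thinning to the lowest of these totals, 29.65 assembled genes on average were found in salt only and 4.4 in control only.

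**Figure D3:**
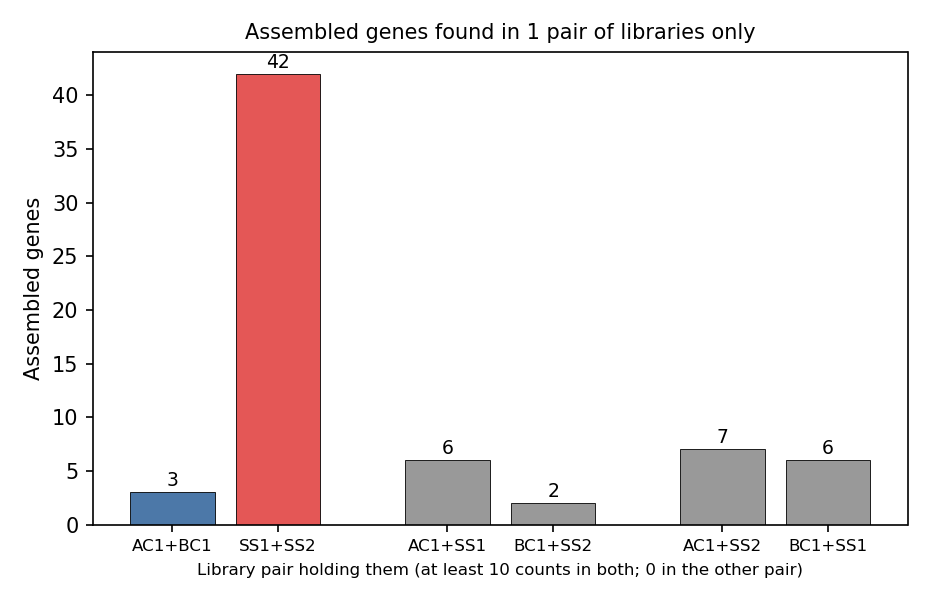
Bars count assembled genes with at least 10 counts in both libraries of a pair and 0 in both others, for the treatment pairing (blue control, red salt) and the 2 other pairings (grey). The salt pair holds 42, and every other pair holds between 2 and 7.

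The assembled genes named by the fixed rule had the largest fitted fold changes in each direction among the 187 tied at the smallest adjusted p. None passed the adjusted threshold in edgeR (adjusted p = 0.448 for each). A treatment at 0 counts makes the fitted fold change large, so the pair lower in salt was picked despite few counts. TR26363|c0_g1, of 1624 bases, had 0 counts in both control libraries and 869 and 239 counts in salt. Its salt level was 111 CPM ± 85.4 (SD, n = 2), at least 126.4-fold higher than the control floor of 3 counts per library (0.88 CPM), or at least 57.7-fold without SS1 and 195-fold without SS2. TR15518|c0_g1, of 1769 bases, had 1 and 0 counts in control and 1843 and 337 in salt, which is 218 CPM ± 207 (SD, n = 2) in salt. The ratio of its pooled scaled counts was 1522, with an exact 95% counting interval of 273 to 60160. It was 488.7 without SS1 (87 to 19359), 2483 without SS2 (445 to 98117) and 740.0 without BC1 (133 to 29243), and at least 254.5-fold without AC1, which held the only control count. The spread of both between SS1 and SS2 exceeded 3-fold. TR27879|c0_g2, of 570 bases, had 12 and 14 counts in control and 0 in both salt libraries, a control level of 3.80 CPM ± 0.26 (SD, n = 2) and at least 6.2-fold above the salt floor of 0.61 CPM. TR20580|c0_g1, of 1320 bases, had 12 counts in each control library and 0 in salt, 3.52 CPM ± 0.14 (SD, n = 2) and at least 5.7-fold above that floor. With DESeq2 the adjusted p was 1.93e-08 for TR26363|c0_g1 and 1.90e-07 for TR15518|c0_g1, and none was given for the pair lower in salt, whose counts are few. With the replicate block in DESeq2, TR26363|c0_g1 no longer passed (adjusted p = 0.292) and TR15518|c0_g1 did (adjusted p = 1.42e-09). The fitted log2 fold change of TR26363|c0_g1 stayed similar, at 10.862 with the block and 11.045 without it. Over the alternatives that gave an adjusted p, the lowest and highest were 1.93e-08 and 1 for TR26363|c0_g1, 1.42e-09 and 1 for TR15518|c0_g1, 0.347 and 1 for TR27879|c0_g2, and 0.367 and 1 for TR20580|c0_g1. In the authors' deposited table of 646, TR26363|c0_g1 and TR15518|c0_g1 are listed as higher in salt, and the other two are not listed.

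**Figure D4:**
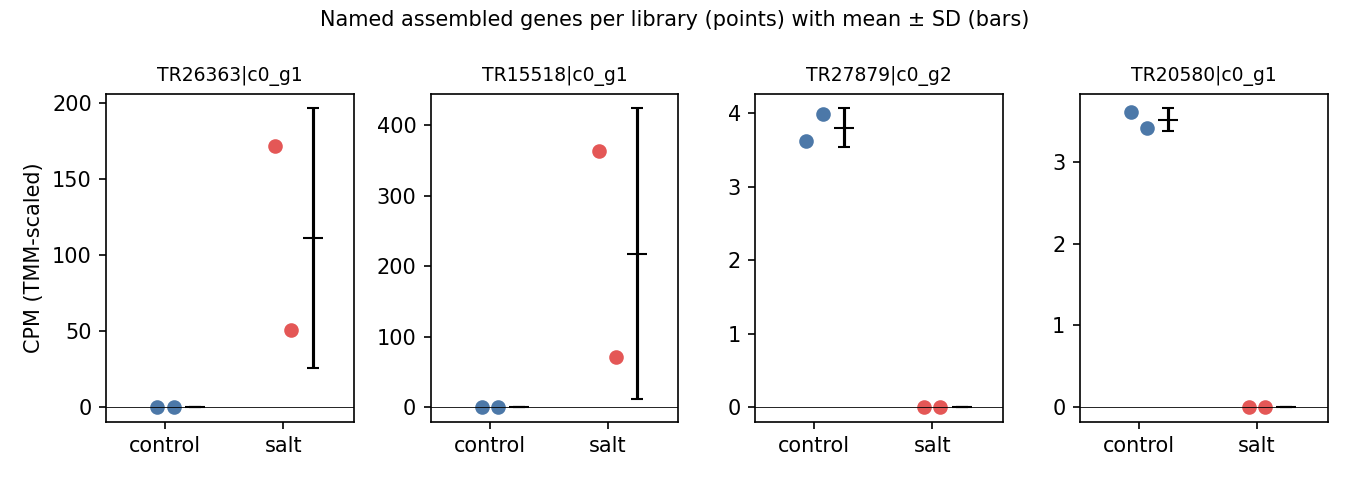
Points give the TMM-scaled CPM of each library for 4 named assembled genes (blue control, red salt), with the mean ± SD of 2 libraries as a black bar, and each panel has its own y axis. TR26363|c0_g1 and TR15518|c0_g1 reach 171 and 364 CPM in SS1 and 50.8 and 71.6 CPM in SS2, and the others stay under 4 CPM.

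The authors' deposited table of 646 assembled genes lists 322 as higher in salt and 324 as higher in control. Its median fold is 2.74 for those higher in salt (quartiles 1.99 and 6.52) and 3.18 for those higher in control (quartiles 2.22 and 5.29), as the authors' deposited table gives them. Of the 646, 634 were tested here with edgeR, and 634 had both salt libraries beyond both control libraries in the listed direction. At an unadjusted p under 0.05 there were 497 of them, and 0 passed the adjusted threshold. The list was chosen on these libraries, so this is not independent evidence of direction. DESeq2 and the authors' deposited table shared 78 assembled genes higher in salt, against 2.72 for independent lists of those sizes, and 75 lower, against 2.84. No assembled gene was called in opposite directions by the DESeq2 fit and the authors' deposited table. These analyses used the same libraries, so part of the overlap can come from their shared chance values, and how much was not measured.

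The authors' deposited Cuffdiff table marks 219 of 26050 loci as significant, with q-values up to 0.046. For 147 of them 1 condition is listed at 0 and the fold change is infinite. The 219 loci lie on 215 assembled genes, of which 47 are in the authors' deposited table of 646, and 86 are among the DESeq2 calls. Among the 21840 assembled genes in both of the authors' deposited tables and tested by Cuffdiff, the 215 and 484 of the 646 would share 4.76 if independent. Among the 15802 tested by both Cuffdiff and DESeq2, 128 of the 215 and 277 of the 345 would share 2.24. These lists too come from the same libraries. All 3 lists held 20 assembled genes that DESeq2 called higher in salt and 20 that it called lower.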

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

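The settings for salt-only and control-only assembled genes, those for the 50 most abundant and the DESeq2 fits without a library or with a block were chosen after the data were seen. The edgeR count of 0 assembled genes stayed at 0 with RLE size factors, with both other filters, with all 3 limma fits on TPM, with the 1.5-fold test, at an adjusted p under 0.01 and with the replicate block. It became 345 with DESeq2, and it ranged from 0 to 1256 when a library was left out: 1256 without AC1, 489 without BC1 and 0 without SS1 or SS2 with edgeR, and 1015, 306, 44 and 88 with DESeq2. A fit with 1 control library takes its spread from the salt pair and assumes that the lone library varies alike. In 5 simulations with no effect, such fits made up to 83 calls. Those simulations gave both treatments the same dispersion, although the control libraries lay further apart, so they set no chance level for such fits. The replicate block (AC1 paired with SS2) gave 0 calls with edgeR and 295 with DESeq2, although the numbers of the salt libraries are in doubt. Deviations of the same-numbered libraries from their group means correlated at 0.09 over 19467 assembled genes, and with 2 pairs the numbers were not taken to pair the libraries. Of the authors' 646 assembled genes, DESeq2 called 153, and 119 with the replicate block. That number was the same without AC1 and smaller without BC1, most so without SS1 or SS2. The salt-only count was 118 at 5 counts and 15 at 20 counts, and 83 to 243 when a library was left out, against 20, 0 and 14 to 47 for control-only. The salt-only count was above the control-only count in each of these settings, while at 5 counts the next pair of libraries held 59. A minimum of 5 counts or a left-out library only relaxes the rule. The original assembled genes stay counted there, so those settings are no separate test of the imbalance. The 50 most abundant assembled genes with both salt libraries lower numbered 9 with library totals and 19 with TMM. The median log2 fold change of the tested assembled genes was -0.05 with edgeR and 0.30 with limma on log2(TPM + 1), which changes several choices at once, and 3682 of 4895 assembled genes at an unadjusted p under 0.05 were then higher in salt, against 782 of 1749 with edgeR. The tests of gene lists were not run, because no ID has a name here. At this depth and with 2 libraries per treatment, edgeR recovered 38.8% of simulated 16-fold and 0.2% of simulated 4-fold changes. Those simulations too gave both treatments the same dispersion. Under that setting, changes of 4-fold or less were mostly not detectable.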

Other observations

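The patterns below were noticed in the data and then tested on the same data. The tests of independent loss and its balance, of a trend with assembled length and of salt-only assembled genes alone in their component were chosen after values they rest on had been seen, namely the numbers of missing assembled genes per library, the correlations of library ratios with length and the numbers of assembled genes per component.

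When each control library was left out in turn, the calls of both edgeR fits overlapped. Among 21992 assembled genes tested in both, 82 were called higher in salt in both fits and 80 lower, where independent lists would share 3.97 and 7.71. A further 22 were called in opposite directions. Both fits used the same salt libraries, and in 5 simulations with no effect they shared at most 15 calls. Those simulations gave both treatments the same dispersion, whereas the SD of the log2 ratio was 1.244 between the control libraries and 0.785 between the salt libraries. The simulated number is therefore not a chance level for the shared calls. BC1 lacked 124 assembled genes that had at least 10 counts in each of the other libraries, AC1 lacked 28, SS2 lacked 15 and SS1 lacked 3.

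The excess of salt-only assembled genes (42 against 3) was weighed against technical sources. Fewer counts outside the abundant assembled genes in control are not the whole source of it. After thinning, the lowest salt-only count over 20 draws was 27 and the highest control-only count was 7. The means after thinning were 29.65 and 4.4, closer together than 42 and 3, so these fewer counts may account for part of the excess. Equal totals outside the abundant assembled genes need not give equal depth for a typical assembled gene, and this was not tested. Independent loss at 1 rate per class of abundance does not give the number: 3.33 of 18053 assembled genes were expected at 0 in both control libraries (95% Poisson range 0 to 7), and 42 were observed. Independent loss at rates that differ between assembled genes of like abundance is not excluded by this. The imbalance stays open, since control-only assembled genes also exceeded their expectation (3 against 0.17, range 0 to 1) and the expected ratio of 19.6 lies within the exact interval of the observed ratio of 14 (4.5 to 70.6). Reads split between assembled copies in the same component are not the whole source, since 12 of the 42 had no other assembled gene in their component. For the 30 that had one they stay open as a candidate explanation: 9 had one with the opposite pattern, between the bounds set in advance, 4 of these with at least 10 counts in both control libraries, and 33 are left without the 9. Both control libraries lay above both salt libraries in 3998 of the 20018 tested assembled genes, so many of the 9 may be background. Copies assembled in other components were not tested, and the salt treatment stays open too.

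The control libraries lay further apart (r = 0.782 across 19467 assembled genes, which are not independent replicates) than the salt libraries (r = 0.903), and by r BC1 stood apart from each other library, at 0.788 with SS1 and 0.789 with SS2, while AC1 was closer to SS1 (0.826) and SS2 (0.857). The median size of the log2 ratio, with libraries scaled to their totals, was 0.655 in control and 0.474 in salt. It was 0.829 and 0.685 from AC1 to SS1 and SS2, and 0.694 and 0.634 from BC1 to them. A shift common to most assembled genes enters this size, and the TMM factors differed (0.723 for AC1, 1.318 for SS1). The SD of the log2 ratio, which such a shift hardly moves, set BC1 apart as r did. It was 1.04 and 0.956 from AC1 to SS1 and SS2, and 1.226 and 1.233 from BC1. The most abundant assembled genes are not the whole cause, as r was 0.764 in control and 0.898 in salt without the top 50. Depth is not the whole cause, as r in control reached at most 0.764 over the thinned draws, with at least 0.894 in salt. A trend with assembled length was removed and left the SD of the control log2 ratio at 1.245, against 0.780 for salt. Differences between plants, library preparation and a wrong label were not tested.

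DESeq2 called 345 assembled genes for salt against control, 134 for AC1 and SS2 against BC1 and SS1, which is the split by replicate number, and 15 for AC1 and SS1 against BC1 and SS2. Among the 3 pairings, 1, the real one, gave as many, and 3 pairings are too few for a share under 0.05. The other pairings mix the treatments, so any salt effect adds to their spread and lowers their calls. In the simulations DESeq2 made on average 70.4 false calls. There 200 assembled genes were changed, and it recovered 17.6% of the 4-fold and 88.2% of the 16-fold changes. In the simulations the false share was thus well above the 0.05 that the threshold sets, so part of the 345 may be false. How large a part was not measured, since the simulations gave both treatments the same dispersion although the control libraries lay further apart.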
